A study of Mus musculus with 5 samples.

How the data were processed

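Single-cell libraries made by inDrop from polyadenylated RNA of dissociated islets were available for 5 samples, 1 non-pregnant, 2 pregnant and 2 postpartum. Per the submitters' processing notes the genome builds were GRCm38 and mm10 and the tools were Partek 8.0 and Bowtie 1.1.1, with no role given for either. The counter, the gene annotation, the cell filters and the feature filters are not given in the sources used here.

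The deposited non-pregnant file holds a linear signal, made by the authors from UMI counts: each cell was divided by its total and multiplied by 1 constant, so that every cell sums to 3023.99 over 40930 features. The deposited pregnant and postpartum files hold log2 of counts per 1000000 plus 1 per cell over 6695 features. In these files the kept features of a cell sum to 616662 to 983713 after back-transformation in pregnant 1, 597621 to 975153 in postpartum 1 and 601795 to 982900 in postpartum 2. In pregnant 2 the sums run from 513885 to 1.00001e+06. UMI counts per cell were recovered as whole multiples of the smallest value of the cell, and 100% of recovered values lay within 0.1 of a whole number (largest deviation 0.0256). The non-pregnant file thus differs from the other 4 in scale, feature list and depth, and the non-pregnant group cannot be told apart from these differences.

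Features were matched by symbol (6543) or by a unique synonym in the annotation (88), giving 6631 shared genes, while 64 stayed unmatched. The shared list holds none of the mitochondrially encoded genes, which took 4.25% of non-pregnant UMIs. Rn45s (5.55%, 0.308%, 0.946% and 1.67% of UMIs in pregnant 1, pregnant 2, postpartum 1 and postpartum 2) and Gm42418 (1.09% of non-pregnant UMIs), which both hold ribosomal RNA sequence, were left out, as were symbols turned into dates (14 in the 4 files, 26 in the non-pregnant one). Scrublet within scanpy 1.11.5 called 5, 1, 1, 17 and 2 doublets in library order, and these 26 of 4687 cells were removed. All other deposited cells were kept. A minimum of 500 UMIs per cell had been intended, but pregnant 2 has 0 and postpartum 1 has 28 such cells, so it became an alternative.

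Cells were clustered on 59 marker genes (square root of counts per 10000, 15 principal components, 20 neighbours, leidenalg 0.10.2 at resolution 0.5). The non-endocrine cluster was split once more with 8 components, 10 neighbours and resolution 1.0. Clusters were named from marker lists of beta, alpha, delta, gamma, ductal, acinar, endothelial, mesenchymal, Schwann, macrophage and other immune and blood cells. Of the listed markers 12 of 12 for beta, 8 of 8 for alpha, 4 of 5 for delta, 5 of 5 for gamma, 12 of 12 for acinar, 8 of 9 for endothelial, 5 of 10 for macrophage, 3 of 8 for ductal and 1 each of 10 for mesenchymal and of 8 for Schwann cells were measured, and no cluster was named ductal, mesenchymal or Schwann. No marker of dendritic, T or NK, B, plasma, neutrophil or erythroid cells was measured, so those classes could not be seen.

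For each class and library the mean over cells of CPM was computed on non-hormone UMIs of the shared genes. The limma test (limma 3.58.1, R 4.3.3) was run on log2 of this mean plus 100 with a trended prior for genes with a mean of at least 100 CPM over the libraries. Each class had 1 fit with the 3 groups and all libraries of at least 10 cells of the class. This leaves 2 residual degrees of freedom in beta-like and alpha-like cells and 1 in delta-like and gamma-like cells, where pregnant 2 was left out. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The lone non-pregnant library is assumed to vary like the other groups. Nothing in the labels says that replicate libraries came from separate animals, so the p-values speak at most for the spread between these libraries. In the beta-like and alpha-like fits with all libraries the prior had infinite weight. The error of a gene there was set by the trend over genes and not by its own spread. In the beta-like fit without pregnant 2 the prior had 85.5 degrees of freedom against 1 residual degree, so the trend set most of the error too. In beta-like cells the non-hormone UMIs numbered 533837, 181085, 2678, 34313 and 146457 in library order, and a count of 0 allows up to 5.62, 16.6, 1120, 87.4 and 20.5 CPM (3 counts, each taken as 1 molecule, which may not hold in pregnant 2). These limits, and ratios to a library with 0 to 3 UMIs, use the UMIs of a class pooled over cells, which weights cells by depth, so they differ from ratios of the CPM levels given as means over cells. Ratios to a library with 1 to 3 UMIs carry an exact binomial interval for the ratio of counts.

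The test planned before the data were examined was edgeR on raw counts, with limma on log2 means as the fallback for normalized files. The deposited files hold normalized values, so limma became the main test, although whole UMIs could be recovered. The gene lists, the marker lists, the rule for named genes and the first set of other settings were also chosen before the data were examined. Under that rule the named genes were, for each comparison in beta-like cells, the 10 with the largest positive and the 10 with the largest negative log2 difference among those called at a mean of 20 CPM or more. Where fewer were called, the genes with the smallest p-values in each direction filled the places and are given as values. Added to these were up to 4 members of each list with the smallest p-values, Tph1, Tph2, Prlr, Ins1, Ins2, Gcg, Sst and Ppy, and in other classes 3 genes per direction and the class markers. Tph2 is in no shared list and has no value. Predicted genes were counted, not named. Gm5148 and H2-Q4 were named outside the rule, after their values were seen, since they fall in counts of 5 or fewer.

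Gene lists were tested in beta-like cells with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, for lists with at least 5 tested members. They were lactogen response and serotonin (9 tested of 24), ER stress and protein folding (22 of 26), secretory granule and hormone processing (22 of 25), beta cell identity and glucose sensing (18 of 23), other islet hormones and exocrine transcripts (5 of 23), nuclear oxidative phosphorylation (35 of 42), ribosomal proteins (61 of 63), immediate early and dissociation stress (17 of 24), cholesterol synthesis (9 of 19), glycolysis (5 of 17) and oxidative stress defence (17 of 20). Cell cycle, mitochondrially encoded, interferon response, antigen presentation, apoptosis and senescence, angiogenic and endothelial signalling, macrophage activation and hormone receptors had too few tested members with all libraries at the main settings. Differences between beta-like and alpha-like cells were tested in limma on the per-library difference of the log2 values, a test chosen after the data were seen.

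The tests were tried on simulated data with the depths of these libraries, a dispersion of 0.05 and 200 changed genes. The simulation drew counts summed per library, each as 1 molecule, with the same unchanged levels in pregnant 2 as elsewhere. Limma on the data used means over cells, and pregnant 2 differs there in more than depth, so these rates need not hold for the data. With all 5 libraries limma recovered 0%, 2.99% and 30.3% of genes changed 2-fold, 4-fold and 8-fold between postpartum and non-pregnant and 4.48%, 22.4% and 53.03% between postpartum and pregnant. Without pregnant 2 it recovered 0%, 58.2% and 77.3%, and 5.97%, 55.2% and 83.3%. With 5 libraries edgeR 4.0.16 recovered 0%, 1.49% and 18.2% between postpartum and non-pregnant and 0%, 0% and 22.7% between postpartum and pregnant, and DESeq2 1.42.0 recovered 0%, 0% and 19.7%, and 1.49%, 8.96% and 39.4%. edgeR without pregnant 2 recovered 0% at each fold in these comparisons, although it called genes in the data. At most 3 unchanged genes were called by limma in any of these runs. Camera at the preset correlation called a list of 20 genes shifted by 1 on the log2 scale (adjusted p = 2.94e-08 and 0.000288 for postpartum against non-pregnant and against pregnant), where an estimated correlation (adjusted p = 0.251 and 0.487) and fry (adjusted p = 0.258 and 0.144) did not, and the preset correlation called 1 of 10 unshifted lists between pregnant and non-pregnant.

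Other settings chosen beforehand were median-of-ratios factors, DESeq2 on recovered UMIs, no minimum level, leaving out each pregnant and postpartum library in turn, fitting only the 2 compared groups, thinning to the lowest depth, a minimum of 1000 UMIs per cell, keeping doublet calls, classes by marker score, a constant 10 times larger or smaller, a replicate block, an estimated correlation and fry. Added after seeing the data were edgeR on the recovered UMIs (planned beforehand for raw counts) with and without pregnant 2, a minimum of 500 UMIs per cell, a minimum mean of 1000 CPM, hormones in the denominator, the deposited scale per cell, and hormones left out of the test. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and BLAST 2.17.0.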

Results

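Transcripts of single cells from dissociated pancreatic islets of C57BL/6 mice were counted by inDrop, a droplet method that tags each molecule with a unique molecular identifier (UMI). There was 1 library of non-pregnant mice, 2 of pregnant mice (pregnant 1 and pregnant 2) and 2 of postpartum mice (postpartum 1 and postpartum 2). In that order the libraries held 847, 1993, 164, 557 and 1126 cells and 2561319, 1136444, 14933, 134957 and 710529 UMIs. The median cell had 2553, 539, 89, 236 and 572.5 UMIs. Transcripts of 8 islet hormones, insulin and glucagon among them, made up 39.1%, 45.1%, 35.6%, 59.3% and 63.6% of the UMIs. The non-pregnant group had no replicate, so its spread was taken to be that of the other groups.

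Pregnant 2 stood apart from the other libraries. It had 1193 detected features, against 6070 to 27309 in the others. In its cells 21.8% of the 1697 detections of a non-hormone gene in a cell held 10 or more counts, against 0.0391% to 0.755% elsewhere, and the mean detection held 5.64 counts, against 1.18 to 1.80. Whether each of these counts is 1 molecule is not known, so limits from a count of 0 in this library may be too low. Genes with a high level in this library could rest on few UMIs: Lurap1l stood at 14387 counts per 1000000 non-hormone UMIs (CPM) from 40 UMIs and Ifngr1, the interferon gamma receptor, at 16326 CPM from 16 UMIs. Lurap1l was at 58.4 to 226 CPM and Ifngr1 at 11.1 to 37.9 CPM in beta-like cells of the other 4 libraries.

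The make-up of the islet cell populations was compared first, to ask which cell types each state contributed. Beta-like cells, which express insulin, were the largest named class in both postpartum libraries, at 65.6% (95% Clopper-Pearson interval 61.4 to 69.6) of 540 and 60.3% (57.4 to 63.2) of 1124 cells. They made up 37.5% (34.2 to 40.9) of 842 non-pregnant cells, 29.8% (27.8 to 31.9) of 1992 cells in pregnant 1 and 30.1% (23.1 to 37.7) of 163 cells in pregnant 2. Alpha-like cells, which express glucagon, made up 10.8% of non-pregnant, 5.92% and 14.7% of pregnant and 19.1% and 14.1% of postpartum cells. Delta-like cells, which express somatostatin, made up 5.70%, 2.26%, 4.91%, 2.78% and 2.85% of cells in the order non-pregnant, pregnant 1, pregnant 2, postpartum 1 and postpartum 2. Gamma-like cells, which express pancreatic polypeptide, made up 3.68%, 2.31%, 1.23%, 2.59% and 2.31% in the same order.

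A further class of barcodes held transcripts of several hormones together. It made up 37.4% (34.1 to 40.8) of the non-pregnant library and 55.4% (53.2 to 57.6) of pregnant 1, but 0.613% (0.0155 to 3.37) of pregnant 2, 2.78% (1.56 to 4.54) of postpartum 1 and 0.979% (0.490 to 1.74) of postpartum 2. In pregnant 1 these barcodes carried 18.7% of their UMIs on Ins2 and 2.48% on Gcg, and in the non-pregnant library 18.5% and 2.37%. A class led by insulin and glucagon made up 15.7% (13.6 to 17.9) of postpartum 2 and 0.613% to 5.0% of the others. In pregnant 2, 46.01% (38.2 to 53.98) of cells fell in no named class, against at most 0.926% elsewhere. Shares were not tested between groups: an exact permutation test of 1 library against 2, or 2 against 2, cannot give a p under 0.05, and no model was fitted to the shares. When classes were assigned by marker score in place of clusters, the beta-like shares became 61.6%, 65.4%, 72.4%, 70.9% and 72.7% in library order. The gamma-like shares became 25.1%, 26.9%, 6.75%, 8.89% and 11.3%, and the alpha-like shares 5.70%, 2.86%, 14.1%, 17.6% and 11.2%.

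**Figure D1:**
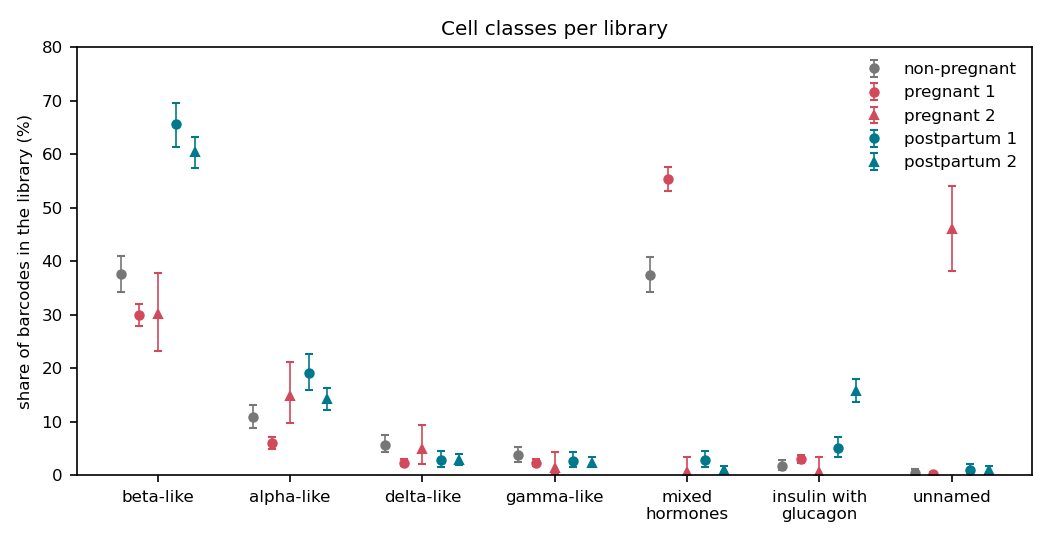
Share of cells (percent, vertical axis) in each class in each of the 5 libraries, with the 95% Clopper-Pearson interval of each share. Beta-like cells stand at 65.6% and 60.3% in the postpartum libraries and at 29.8% to 37.5% in the other 3, and barcodes with several hormones stand at 37.4% and 55.4% in the non-pregnant and pregnant 1 libraries.

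Endothelial-like cells numbered 12, 9, 0, 3 and 12 in the order non-pregnant, pregnant 1, pregnant 2, postpartum 1 and postpartum 2, macrophage-like cells 3, 10, 0, 2 and 15, and acinar-like cells 9, 4, 3, 2 and 5. These classes were too small to test. The 0 of 163 cells for endothelial-like and macrophage-like cells in pregnant 2 allows a share of up to 1.84% by the limit of 3 counts (2.24% by the exact interval). None of the 14 genes chosen to mark dividing cells was among the genes that all files shared, so cycling beta-like cells could not be counted. All intervals and lower limits cover counting error only.

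Within beta-like cells the insulin transcripts took the largest part of the UMIs. Ins2 made up 21.1% of UMIs in the non-pregnant library, 25.1% and 25.03% in the pregnant and 35.03% and 44.1% in the postpartum libraries. Ins1 made up 11.3%, 17.2%, 12.5%, 17.1% and 19.9% in library order. Iapp, which encodes the amyloid peptide released with insulin, made up 7.75%, 5.39%, 7.63%, 8.36% and 2.95%. In alpha-like cells, which should lack insulin, Ins2 made up 0.176% to 0.863%. Beta-like cells fell into 3 clusters that the libraries filled unequally. The cluster led by Fmo1, Prlr, Ivd, Fosb and Enpp2 held 550 of 678 beta-like cells of postpartum 2, 35 of 354 of postpartum 1, and 3, 20 and 13 of the non-pregnant, pregnant 1 and pregnant 2 libraries. The cluster led by Pdyn, Wipi1 and Nkx6-1 held 273 of 316 non-pregnant beta-like cells, 262 of 594 and 26 of 49 of the pregnant ones, and 19 and 16 of the postpartum ones. The last cluster, led by Mafa, Prlr and Prkcb, held 40, 312, 10, 300 and 112 in library order. Leading genes were ranked on UMIs pooled over a cluster against all other cells, without adjustment for library. Of the 621 cells of the cluster led by Fmo1, 550 were from postpartum 2, so its leading genes cannot be told apart from that library. Mafa, Nkx6-1, Ins1, Ins2 and Iapp, whose levels differed between libraries, were among the clustering markers.

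The comparison of pregnant with non-pregnant beta-like cells asked which transcripts differ in pregnancy. Mafa, a transcription factor of mature beta cells that activates the insulin genes, stood at 1267 and 2758 CPM in the pregnant libraries and at 3.03 CPM, from 1 UMI, in the non-pregnant one. From UMIs pooled over the cells, 231 against 1, the ratio of pregnant 1 to non-pregnant was 681 (counting interval 121 to 27012). Ptprn2, a membrane protein of secretory granules, stood at 1044 CPM in pregnant 1 against 38.3 CPM. Zc3h11a, a zinc finger protein of messenger RNA export, stood at 705 against 23 CPM. In pregnant 2 the latter pair rested on 1 UMI each. Tpt1, the translationally controlled tumour protein, stood at 4388 CPM in the non-pregnant library, at 39.8 CPM in pregnant 1 and at 0 in pregnant 2, where a count of 0 allows up to 1120 CPM if each count is 1 molecule. Gpx4, which reduces lipid peroxides, went from 1006 to 59.2 CPM between the non-pregnant and pregnant 1 libraries. Rps6, a protein of the small ribosomal subunit, went from 847 to 30.5 CPM, and the transcription factor Zbtb20 from 857 to 54.8 CPM. All the genes named so far differed from the non-pregnant library in the same direction in both postpartum libraries, as Mafa at 1856.5 and 1406 CPM. The non-pregnant file was made differently, so these differences cannot be ascribed to pregnancy. Prlr, the prolactin receptor, stood at 2021 CPM and, from 6 UMIs, at 3447 CPM in the pregnant libraries against 1349 CPM. Relative to non-hormone UMIs, Ins1 was 1.66 ± 0.69 (SE) and Ins2 1.23 ± 0.58 higher on the log2 scale in pregnancy. In pregnant 2 these are means of ratios to few non-hormone UMIs, over 49 cells with a median of 83 UMIs. By share of pooled UMIs Ins1 stood at 12.5% in pregnant 2, 17.2% in pregnant 1 and 11.3% in the non-pregnant library. Without pregnant 2 both differences were smaller, as given below.

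None of 2116 genes passed the limma test between pregnant and non-pregnant beta-like cells at a Benjamini-Hochberg adjusted p of 0.05, with 31 genes at an unadjusted p under 0.05. With edgeR none of 5412 genes was called (77 unadjusted), and of 6630 genes DESeq2 called Mafa alone (78 unadjusted). In all 3 comparisons each tool had a smaller share than 0.05 of its genes at an unadjusted p under 0.05. Those counts therefore point to no further genes. The count changed with depth and with the libraries kept: limma called 94 genes (7 higher, 87 lower) with all 5 libraries thinned to the lowest depth, 46 of 2458 genes (20 higher, 26 lower) without pregnant 2, edgeR called 111 without it, and limma called 1519 without pregnant 1. Thinning leaves each library at 2678 non-hormone UMIs, where a count of 0 allows up to 1120 CPM. Ties at few UMIs can then make the spread of a gene vanish. How many calls had a whole group at 0 after thinning was not counted. The fit without pregnant 2 sets 1 library against 1, and only the postpartum pair gives it a residual. Its prior had 85.5 degrees of freedom against 1 residual degree. The error of a gene was thus set almost wholly by the trend over genes, in all 3 comparisons. Its p-values do not measure a gene's own spread between libraries. In it limma gave Mafa a log2 difference of 3.73 ± 0.50 (adjusted p = 5.65e-08; higher in both pregnant libraries, with 10 UMIs in pregnant 2), a value that depends on the added constant since Mafa has 1 UMI in the non-pregnant library. Ptprn2 differed by 3.05 ± 0.51 (limma adjusted p = 1.49e-05) and Zc3h11a by 2.71 ± 0.52 (limma adjusted p = 0.000311). Tpt1 was at -5.00 ± 0.54 (limma adjusted p = 3.46e-11). It and the next 3 genes were lower in pregnant 1 and had no UMI in pregnant 2, whose limit of 1120 CPM lies above the non-pregnant levels of the latter 3. Rps6 was at -2.86 ± 0.59 (limma adjusted p = 0.00141), Gpx4 at -2.80 ± 0.59 (limma adjusted p = 0.00175) and Zbtb20 at -2.63 ± 0.58 (limma adjusted p = 0.00279). Insulin and Prlr did not pass there: Ins1 differed by 0.83 ± 0.52, Ins2 by 0.49 ± 0.54 and Prlr by 0.55 ± 0.47, each with a limma adjusted p of 0.998. In the GRCm38.p6 annotation Mafa lies on chromosome 15 from 75745501 to 75748321 and Tpt1 on chromosome 14 from 75845256 to 75848303.

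Of the gene lists fixed beforehand, the ribosomal proteins passed camera at a preset correlation as lower in pregnancy (adjusted p = 1.67e-10), but not camera with an estimated correlation (adjusted p = 0.963) or fry (adjusted p = 0.608). Of 61 tested ribosomal members 55 had a log2 difference under 0, with a median of -1.84, while 0 passed limma over all genes and 4 were lower adjusted over the list alone. Some members, Rps6 among them, share a near-identical stretch at the end of their transcript with a transcript of another gene. The median of all tested genes was itself -0.72 in this comparison, -0.01 between postpartum and non-pregnant and 0.70 between postpartum and pregnant, and counts of members higher or lower here and below are against 0. Most members of the other lists were lower as well, such as 34 of 35 for oxidative phosphorylation and 16 of 17 for the immediate early list. Without pregnant 2 the median of all tested genes was 0.02. Of 36 oxidative phosphorylation members 24 were then higher and 12 lower, and of 18 immediate early members 5 were higher and 13 lower. Without pregnant 2 the ribosomal median was -0.50, with 45 of 61 members lower, 12 of them called by limma over all genes and 18 adjusted over the list alone, and 16 higher, of which 3 and 4 were called. The immediate early and dissociation stress list (median -0.84), the secretory granule list (median -1.16) and the oxidative phosphorylation list (median -0.93) gave camera adjusted p-values of 0.883, 0.883 and 0.299, the last of which became 0.0176 without pregnant 1. The lactogen response and serotonin list, whose genes follow prolactin signalling, had a median of -0.72 (limma camera adjusted p = 0.563), and its member Wipi1, an autophagy protein, was lower adjusted over the list alone. ER stress and protein folding (median -1.11), cholesterol synthesis (median -0.70) and oxidative stress defence (median -0.74) gave camera adjusted p-values of 0.563, 0.906 and 0.857. Beta cell identity (median -0.88), the other islet hormones and exocrine transcripts (median -0.81) and glycolysis (median -1.61) gave 0.909 each by camera. The camera direction was up, against the median's sign, for secretory granule, identity, other hormones, cholesterol and glycolysis. Without pregnant 2 the medians were 0.11 for secretory granule, 0.16 for oxidative phosphorylation, 0.15 for identity, 0.24 for oxidative stress defence and 0.02 for lactogen response. They were -0.21 for ER stress, -0.21 for the immediate early list, -0.06 for cholesterol synthesis and -0.05 for other hormones.

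The comparison of postpartum with non-pregnant beta-like cells asked which differences from non-pregnant islets are present after birth. Here too the state cannot be told apart from the making of the non-pregnant file. Ubb, a ubiquitin gene, stood at 11226 and 12201 CPM in the postpartum libraries against 195 CPM in the non-pregnant one. The immediate early transcription factors Fos and Jun stood at 1871 and 1913 CPM and at 2194 and 2137 CPM, against 119.7 and 150.3 CPM, and Fosb at 809 and 1563 against 16.7 CPM. Mafa stood at 1856 and 1406 CPM, and from pooled UMIs (1923 and 1488 CPM) its ratio to the non-pregnant library was 1027 (178 to 41164) and 795 (141 to 31528). Prlr stood at 6817 and 7333 CPM against 1349 CPM. Ivd, an enzyme of leucine breakdown, stood at 729.7 and 1133 against 113 CPM, and Fmo1, a flavin monooxygenase, at 789 and 1823 against 54.6 CPM. Tpt1 was at 24.8 and 12.8 CPM against 4388 CPM, with the non-pregnant library 152 (27.3 to 6022) and 217 (74.1 to 1052) times higher by pooled UMIs. B2m, the light chain of class I antigen presenting molecules, was at 110.0 and 128 against 1844 CPM.

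None of the 2116 genes passed limma between postpartum and non-pregnant beta-like cells (24 at an unadjusted p under 0.05) and edgeR called none (148 unadjusted). DESeq2 called 4 genes (97 unadjusted): Fosb, Mafa and the predicted gene Gm5148, named after its value was seen, were higher and Tpt1 was lower. Without pregnant 2, which is in neither group but widens the pooled spread, limma called 134 genes (57 higher, 77 lower) and edgeR 317, and without pregnant 1 limma called 126. With all libraries thinned to the lowest depth limma called 181 genes (97 higher, 84 lower), under the limits of thinning given above. In the fit without pregnant 2 Ubb was 5.32 ± 0.41 higher on the log2 scale (limma adjusted p = 7.99e-19; higher in 2 of 2 postpartum libraries, as for each gene here), where the error with all libraries was 1.80. Jun, Fos and Ptprn2 were 3.18 ± 0.44, 3.18 ± 0.44 and 3.25 ± 0.44 higher, each at a limma adjusted p of 5.59e-08, and Fmo1 3.08 ± 0.46 (limma adjusted p = 4.76e-07). Prlr was 2.31 ± 0.41 higher (limma adjusted p = 1.74e-05) and Ivd 2.24 ± 0.45 (limma adjusted p = 0.000248). The insulin genes passed as well, Ins2 at 1.62 ± 0.47 (limma adjusted p = 0.0206) and Ins1 at 1.41 ± 0.45 (limma adjusted p = 0.0469), and so did Ero1lb, an oxidase that folds proinsulin, at 1.67 ± 0.41 (limma adjusted p = 0.00373). Among lower genes B2m was at -3.15 ± 0.44 (limma adjusted p = 6.24e-08), Nkx6-1, a beta cell transcription factor, at -2.11 ± 0.48 (limma adjusted p = 0.00147), and Cpe, the carboxypeptidase that trims prohormones, at -2.04 ± 0.43 (limma adjusted p = 0.000456). Ubb, Zc3h11a, Gpx4 and Rps6 share a near-identical stretch at the end of their transcript with an annotated transcript of another gene, and Mafa, Ptprn2, Tpt1 and Zbtb20 have none. Ubb lies on chromosome 11 from 62551171 to 62553213, Prlr on chromosome 15 from 10177238 to 10349190 and B2m on chromosome 2 from 122147687 to 122153082.

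**Figure D2:**
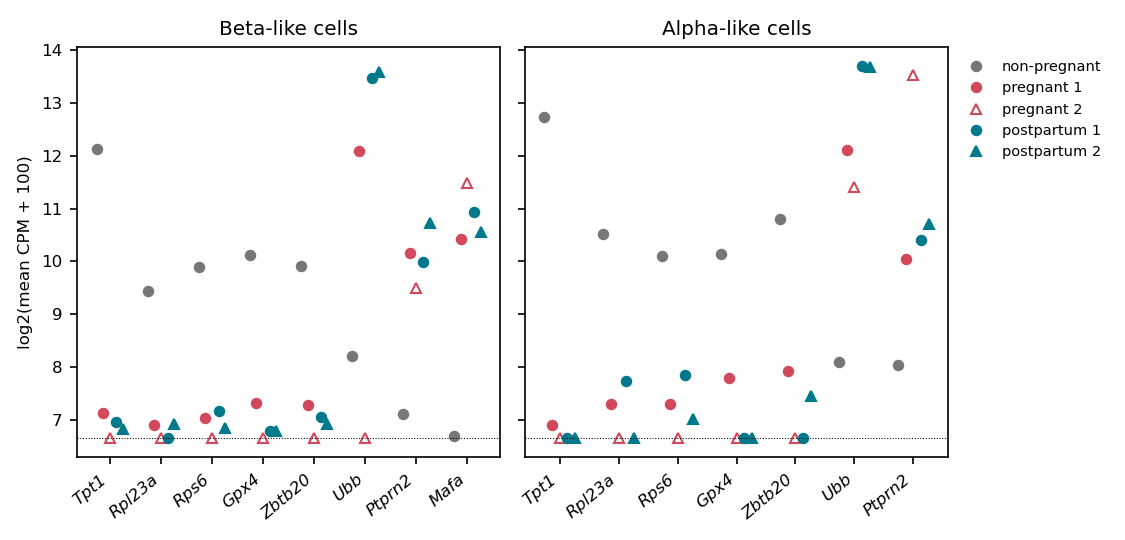
Level of 8 genes, as log2 of mean CPM plus 100 (vertical axis), in beta-like and alpha-like cells, with 1 point per library (grey, non-pregnant; red, pregnant 1 as circle and pregnant 2 as open triangle; teal, postpartum 1 as circle and postpartum 2 as triangle; dotted line, 0 CPM). Tpt1 stands at 4388 CPM in non-pregnant beta-like and 6669 CPM in non-pregnant alpha-like cells and at most at 39.8 CPM in the other libraries, and Ubb stands at 195 and 171 CPM there and at 4236 CPM or more in pregnant 1 and postpartum cells; Mafa is drawn for beta-like cells alone.

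As groups in postpartum against non-pregnant beta-like cells, the ribosomal proteins were lower (54 of 61 members, median -1.23) and the immediate early genes higher (15 of 17, median 1.30). The camera test gave adjusted p = 5.63e-21 and 5.97e-10 at the preset correlation, and adjusted p = 0.625 with an estimated correlation for each, while fry gave 0.993 and 0.79. Of the immediate early members 0 passed limma over all genes or over the list alone with all libraries, and 8 passed over all genes and 10 adjusted over the list alone without pregnant 2. Of the ribosomal members, 4 were lower adjusted over the list alone, and without pregnant 2 limma called 28 lower and 3 higher over all genes and 38 lower and 3 higher adjusted over the list alone. The 5 glycolysis genes tested, Aldoa, Gpi1, Pgk1, Pkm and Tpi1, were all lower (median -0.97; camera adjusted p = 0.0105, and adjusted p = 0.625 with an estimated correlation; fry 0.0868). Secretory granule genes passed camera upward (adjusted p = 0.0227, and adjusted p = 0.625 with an estimated correlation; fry 0.993) with 12 of 22 members higher, a median of 0.04 and a mean of 0.28. Camera no longer called them without pregnant 1 (adjusted p = 0.244) or pregnant 2 (adjusted p = 0.21). The lactogen response list had 7 of 9 members higher (median 0.78; camera adjusted p = 0.317). It passed camera without pregnant 1 (adjusted p = 0.00738) or without pregnant 2 (adjusted p = 0.00604). Without pregnant 2 limma called Prlr and Ivd higher and Wipi1 lower over all genes, and 4 members were higher adjusted over the list alone. Camera gave adjusted p-values of 0.9 for ER stress (median -0.06) and for the other islet hormones and exocrine transcripts (median -0.81), 0.475 for beta cell identity (median 0.22) and 0.723 for oxidative phosphorylation (median -0.12). Cholesterol synthesis (median -0.30) and oxidative stress defence (median -0.04) gave 0.576 and 0.317 by camera.

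The comparison of postpartum with pregnant beta-like cells asked what differs between the states, in 4 libraries whose files share 1 feature list and 1 scale. Genes of the immediate early response stood higher postpartum: Jun at 2194 and 2137 CPM against 59.1 and 0 CPM, Fos at 1871 and 1913 against 166 and 0 CPM, and Fosb, with no UMI in either pregnant library, by pooled UMIs (1107 and 1584 CPM) at least 66.8-fold and 95.6-fold above the limit of pregnant 1 (3 counts per library, 16.6 CPM). Genes known to respond to prolactin did as well: Prlr stood at 6817 and 7333 CPM against 2021 CPM in pregnant 1 and 3447 CPM in pregnant 2. Cish, an inhibitor of cytokine signalling, stood at 323 and 566 CPM against 21.2 CPM from 2 UMIs in pregnant 1. By pooled UMIs (321 and 423 CPM postpartum) the ratios were 29.03 (6.33 to 269) and 38.3 (10.2 to 324). Socs3, another inhibitor of cytokine signalling, belongs to the immediate early and dissociation stress list and not to the lactogen list. Its pooled ratios to pregnant 1 were 26.4 (5.62 to 248) and 35.9 (9.49 to 303), also from 2 UMIs there. Enpp2, the enzyme that makes lysophosphatidic acid, stood at 2521 and 2969.6 CPM against 699.9 and 0 CPM, and the chaperone Hspa5 at 7903 and 7358 against 3344 and 434 CPM. B2m stood at 110.0 and 128 CPM against 2348 CPM in pregnant 1 and 0 in pregnant 2. Tph1, the enzyme that starts serotonin synthesis, had 2 and 32 UMIs postpartum (61.6 and 180.1 CPM) against 2 and 0 in pregnancy and 6 in the non-pregnant library, and the level of postpartum 1 was under its 3-count limit of 87.4 CPM.

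None of the 2116 genes passed limma between postpartum and pregnant beta-like cells (60 at an unadjusted p under 0.05), edgeR called none (77 unadjusted), and DESeq2 called Fosb alone (87 unadjusted). Without pregnant 2 limma called 33 genes (17 higher, 16 lower) and edgeR 69, and without pregnant 1 limma called 1760. After thinning all libraries to the lowest depth limma called 180 genes (162 higher, 18 lower), under the same limits of thinning. Jun was 4.17 ± 1.35 higher with all libraries (limma adjusted p = 0.847) and 3.83 ± 0.44 without pregnant 2 (limma adjusted p = 3.75e-10), higher in 2 of 2 postpartum libraries, as were the genes that follow. Without pregnant 2 Fos was 2.90 ± 0.44 higher (limma adjusted p = 1.27e-06), Nfkbia, an inhibitor of NF-kappa B, 2.56 ± 0.44 (limma adjusted p = 4.19e-05). Ivd was higher by 2.14 ± 0.45 (limma adjusted p = 0.00215), Fmo1 2.13 ± 0.46 (limma adjusted p = 0.0023) and Enpp2 1.83 ± 0.42 (limma adjusted p = 0.00562). Prlr was 1.76 ± 0.41 higher (limma adjusted p = 0.00564) and 1.39 ± 1.43 with pregnant 2 kept (limma adjusted p = 0.847). Fosb, Cish and Socs3 passed limma without pregnant 2 (adjusted p = 1.36e-08, 0.00361 and 0.00361; ratios above), and Ubb was 1.44 ± 0.41 higher (limma adjusted p = 0.046). B2m was at -3.48 ± 0.44 (limma adjusted p = 7.39e-09) without pregnant 2, at -1.18 ± 1.35 with it (limma adjusted p = 0.847) and at 1.13 without pregnant 1. Values that did not pass without pregnant 2 were Hspa5 at 1.17 ± 0.40 (limma adjusted p = 0.188), Ins2 at 1.14 ± 0.47 (limma adjusted p = 0.319) and Ins1 at 0.57 ± 0.45 (limma adjusted p = 0.835). Tph1 was under the limma minimum and was called by edgeR without pregnant 2 between postpartum and pregnant (adjusted p = 0.0255) and between postpartum and non-pregnant (adjusted p = 0.000326), not between pregnant and non-pregnant (adjusted p = 0.995). Jun lies on chromosome 4 from 95049036 to 95052222, Fos on chromosome 12 from 85473890 to 85477274, Fosb on chromosome 7 from 19302696 to 19310118 and Enpp2 on chromosome 15 from 54838901 to 54952789.

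**Figure D3:**
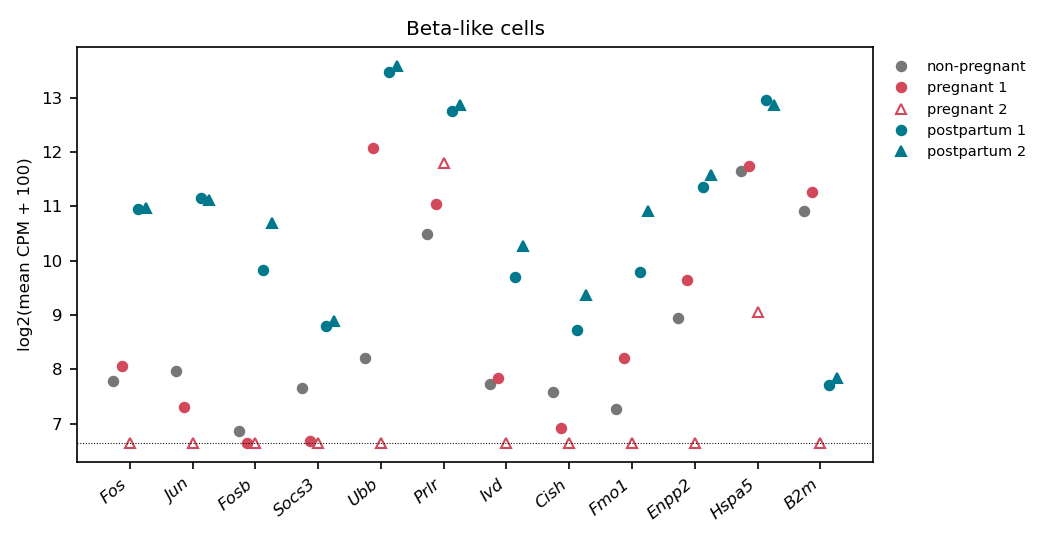
Level of 12 genes in beta-like cells, as log2 of mean CPM plus 100 (vertical axis), with 1 point per library (grey, non-pregnant; red, pregnant 1 as circle and pregnant 2 as open triangle; teal, postpartum 1 as circle and postpartum 2 as triangle; dotted line, 0 CPM). Fos, Jun, Prlr and Enpp2 stand higher in both postpartum libraries than in the non-pregnant and pregnant 1 libraries, as at 2194 and 2137 CPM against at most 150.3 CPM for Jun, and B2m stands at 110.0 and 128 CPM against 1844 CPM in the non-pregnant and 2348 CPM in the pregnant 1 library.

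As groups, the immediate early genes rose in postpartum against pregnant beta-like cells by camera, with 17 of 17 members higher and a median of 1.95, the same with Fosb placed at its lower limit. The adjusted p was 6.07e-09 by camera at the preset correlation, and adjusted p = 0.932 with an estimated correlation (fry 0.25). Of these members 0 passed limma over all genes and 3 adjusted over the list alone, while without pregnant 2 these numbers were 8 and 11 of 18 and the median was 1.51. The lactogen response list had 9 of 9 members higher, with a median of 1.40 (camera adjusted p = 0.0333, and adjusted p = 0.932 with an estimated correlation; fry 0.3). Without pregnant 2 this list had 7 of 9 members higher and a median of 1.13 (camera adjusted p = 6.86e-07), with Prlr, Ivd and Cish called by limma over all genes and 5 members adjusted over the list alone. Camera no longer called it without pregnant 1 (adjusted p = 0.354) or without postpartum 2 (adjusted p = 0.0935). Its members Irs2, an insulin receptor substrate, and Socs2 stood at 1.35 ± 0.52 and 1.13 ± 0.45 without pregnant 2 (limma adjusted p = 0.279 and 0.3). The lactogen response genes were higher in the same libraries in which the immediate early and dissociation stress genes were. Glycolysis passed camera downward (adjusted p = 0.0333, and adjusted p = 0.932 with an estimated correlation; fry 0.123) with a mean of -0.76 but a median of 0.09 and 3 of 5 members higher. It did not pass camera without pregnant 1 (adjusted p = 0.185) or postpartum 2 (adjusted p = 0.0935).

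Ribosomal proteins had a fitted median of 0.53 between postpartum and pregnant beta-like cells (limma camera adjusted p = 0.405, direction down) and of -0.53 without pregnant 2, where 53 of 61 were lower (camera adjusted p = 4.54e-07). ER stress and protein folding had a median of 1.08 with all libraries (limma camera adjusted p = 0.396), with the chaperone cofactor Dnajc3 at 1237 and 1138 CPM postpartum against 409 CPM in pregnant 1. Secretory granule genes (median 0.99), oxidative phosphorylation (median 0.99) and beta cell identity (median 0.94) gave camera adjusted p-values of 0.267, 0.267 and 0.55, and oxidative phosphorylation 0.0434 without pregnant 1. The other islet hormones and exocrine transcripts (median -0.04), cholesterol synthesis (median 0.58) and oxidative stress defence (median 0.66) gave 0.768, 0.396 and 0.768 by camera. The median of all tested genes was 0.70 with all libraries and -0.04 without pregnant 2. List medians with all libraries thus include a shift shared by all genes that was absent without that library. A further 8 lists had fewer than 5 tested genes with all libraries and got no test there. They were cell cycle (3 tested of 5 measured), mitochondrially encoded genes (0 of 0), interferon response (4 of 8), antigen presentation (4 of 10), apoptosis and senescence (2 of 12), angiogenic signalling (2 of 15), macrophage activation (2 of 9) and hormone receptors (4 of 7). The last list reached 5 tested genes without pregnant 2, with limma camera adjusted p-values of 0.809, 0.898 and 0.944 in the 3 comparisons, and with median-of-ratios factors (0.963, 0.998 and 0.905). In the antigen presentation list, B2m was low postpartum while the class I heavy chain H2-K1 stood at 2553 and 2304 CPM postpartum against 3501 and 4274 CPM in pregnancy and 1580.4 CPM in the non-pregnant library.

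Alpha-like cells were compared to ask whether the differences reach beyond beta cells. Ubb stood at 13272 and 12997 CPM in postpartum alpha-like cells against 4336 and 2604 CPM in the pregnant and 171 CPM in the non-pregnant libraries. Fosb stood at 2132 and 2989.7 CPM postpartum against 0 in both pregnant libraries and 13.7 CPM in the non-pregnant one, and the heat shock gene Hspa1a at 766 and 1105 CPM against 0 and 21.4 CPM. Tpt1 fell from 6669 CPM, or 721 UMIs, in the non-pregnant library to 1 UMI in pregnant 1 and none in the other 3, whose 3-count limits were 2147, 302 and 74.1 CPM for pregnant 2, postpartum 1 and postpartum 2. Gcg, which defines the class, stood at 1408060 and 1444890 CPM of non-hormone UMIs postpartum, at 571709 and 808947 in pregnancy and at 418788 in the non-pregnant library.

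Of 1973 genes in alpha-like cells limma called 2 between pregnant and non-pregnant (Gcg, Tpt1; 19 at an unadjusted p under 0.05), the same 2 genes between postpartum and non-pregnant (22 unadjusted) and Gcg between postpartum and pregnant (49 unadjusted). The limma adjusted p of Tpt1 was 0.0441 and 0.0302. The limma error of Gcg came from the trend over genes, so its calls do not measure its own spread between libraries. With edgeR 0 genes were called in each comparison (8, 13 and 16 unadjusted), and DESeq2 called 0 as well (28, 42 and 44 unadjusted). Without pregnant 2 limma called 0 genes, 3 genes (Gcg, Tpt1 and Ubb) and 0 genes in the 3 comparisons, and edgeR 33, 113 and 29. Without pregnant 1 the limma counts were 0, 0 and 448, without postpartum 1 they were 0, 1 and 1, and without postpartum 2 they were 1 (H2-Q4, named after its value was seen), 7 and 13, of which 1, 3 and 9 had a whole group at 0 UMIs. Ubb was at 5.61 without pregnant 2 (limma adjusted p = 0.0094; higher in 2 of 2 postpartum libraries), and Fosb at 4.71 ± 1.56 between postpartum and pregnant did not pass (limma adjusted p = 0.903). Ttr, the thyroid hormone carrier that marks alpha cells, stood at 74956 and 70376 CPM postpartum against 17174 to 21229 CPM elsewhere, which did not pass limma either (postpartum against pregnant 1.92 ± 0.78, adjusted p = 0.903). A test of whether the difference itself differed between beta-like and alpha-like cells, chosen after the data were seen, called 0 of 1453 genes by limma in each comparison with all libraries (1, 12 and 56 unadjusted for pregnant against non-pregnant, postpartum against non-pregnant and postpartum against pregnant). Without pregnant 2 it called 0, 3 (Ins1, Ins2 and Enpp2) and 0, with 5, 56 and 90 unadjusted.

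Delta-like and gamma-like cells were compared without pregnant 2, which had 8 and 2 such cells. In delta-like cells Ubb stood at 7602 and 9914 CPM postpartum, 4298 CPM in pregnant 1 and 313 CPM in the non-pregnant library. The long noncoding RNAs Meg3 and Malat1 stood at 11359 and 12392 CPM and 16398 and 13322 CPM postpartum, against 2139 and 1968 CPM in the non-pregnant library. In gamma-like cells Ubb stood at 8268 and 7980.2 CPM postpartum, 6449 CPM in pregnant 1 and 204 CPM in the non-pregnant library. Meg3 stood at 14716 and 13591 CPM postpartum against 1189 CPM in pregnant 1 and 2314 CPM in the non-pregnant library. In delta-like cells limma called 0 of 2353 genes in each comparison (101, 197 and 202 at an unadjusted p under 0.05), edgeR 0 (14, 28 and 15 unadjusted) and DESeq2 0 (7, 16 and 4 unadjusted). Without pregnant 1, 74 genes were called by limma between postpartum and non-pregnant, but 68 of these, all lower, had a whole group at 0 UMIs. In gamma-like cells limma called 63, 102 and 193 of 2238 genes, but each of these had a whole group at 0 UMIs, and edgeR (14, 33 and 7 unadjusted) and DESeq2 (8, 15 and 3 unadjusted) called 0. That group was postpartum, the only group with 2 libraries in this fit, and it is not part of the pregnant against non-pregnant comparison. The 2 postpartum libraries give the fit its only residual, which is 0 for such genes. With 14 and 26 postpartum gamma-like cells, those genes were not detected there at this depth, and the limma counts became 0 at a minimum mean of 1000 CPM.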

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

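The test between beta-like and alpha-like cells was chosen after the data were seen. Enpp2, which encodes the enzyme autotaxin, was picked out because its difference between postpartum and non-pregnant cells was itself different in beta-like and alpha-like cells. The difference of the differences was 2.86 ± 0.65 on the log2 scale without pregnant 2 (limma adjusted p = 0.00874), and with all libraries limma called 0 of 1453 genes (12 at an unadjusted p under 0.05). In beta-like cells Enpp2 stood at 2521 and 2969.6 CPM in the postpartum libraries and 396 CPM in the non-pregnant one, and in alpha-like cells at 0 and 92.98 CPM against 76.8 CPM. The alpha-like values are near or under the 3-count limits of 302 and 74.1 CPM in the postpartum libraries. Ins1 and Ins2 passed the same test but define the beta-like class. No explanation of the Enpp2 difference was tested.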

How the results depend on the processing

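Alternatives added after the data were seen were edgeR (planned beforehand for raw counts) with and without pregnant 2, the minimum of 500 UMIs, the minimum mean of 1000 CPM, hormones in the denominator, the deposited scale and hormones left out of the test. Counts below are for pregnant against non-pregnant, postpartum against non-pregnant and postpartum against pregnant, in that order. Depth limits pregnant 2 most: it has 2678 non-hormone UMIs in beta-like cells. Where a cause is not given, the cause was not tested. In delta-like and gamma-like cells, counts without a minimum level are nearly all genes with the whole postpartum group at 0. Here and below a whole group at 0 was counted only for groups with at least 2 libraries in the fit. Such a group need not be part of the comparison. Leaving out a library also changes which genes reach the minimum. Keeping doublet calls, hormones in the denominator and the deposited scale gave the same beta-like counts of 0. Of 268 values for gene lists under alternatives 208 stayed the same, 8 newly passed and 22 no longer passed. Another 30 moved, meaning that the camera direction turned without a call in either fit. The direction turned with a call (reversed) in 0. A change in the sign of a list median was not counted. Of 4147 for named genes 3282 stayed the same, 379 newly passed and 485 moved. Without a call, a value within 1 SE of the main one counted as the same and a larger change as moved, whatever its sign. Only 1 reversed with a call, B2m between postpartum and pregnant, at 1.13 without pregnant 1 and -3.48 without pregnant 2 (-1.18 with all libraries). The value of 1.13 rests on pregnant 2, with no B2m UMI and a limit of 1120 CPM above the postpartum levels, so no direction was measured.

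In beta-like cells (0, 0 and 0 called by limma, with 31, 24 and 60 at an unadjusted p under 0.05), median-of-ratios factors gave 2 (Ins1, Ins2) for postpartum against non-pregnant and 1 (Ins2) for postpartum against pregnant. DESeq2 gave 1, 4 and 1. No minimum level gave 3 and 3 (Ins1, Ins2 and Tpt1 each) against non-pregnant. Thinning to the lowest depth gave 94, 181 and 180, where a count of 0 allows up to 1120 CPM in every library. Calls with a whole group at 0 after thinning were not counted. The constant 10 times larger gave 2 and 2 (Rpl23a, Tpt1) against non-pregnant, and 10 times smaller gave 1 (Pcsk2) for postpartum against pregnant. Fitting only the 2 groups gave 137 for postpartum against non-pregnant, with pregnant 2 out of the pooled spread by construction. Classes by marker score gave 3 (Ins1, Ins2, Ubb) there. edgeR without pregnant 2 gave 111, 317 and 69. The minimum of 500 UMIs, which drops pregnant 2 by construction, gave 3 (Mafa, Rpl41, Ubb), 12 and 3 (B2m, Fosb, Jun). The minimum mean of 1000 CPM gave 1 (Ubb) for postpartum against non-pregnant and 3 (Malat1, Pcsk2, Ubb) for postpartum against pregnant, and hormones left out of the test gave 1 (Pcsk2) there. Genes named here outside the rule were named after their values were seen. Leaving out 1 library at a time gave 0 to 1519, 0 to 134 and 0 to 1760.

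In alpha-like cells (2, 2 and 1), median-of-ratios factors gave 0 and 0 against non-pregnant, no minimum level 342, 339 and 0 (all 342 and 339 with a whole group at 0), DESeq2 0, 0 and 0, edgeR 0, 0 and 0, edgeR without pregnant 2 33, 113 and 29, and the minimum mean of 1000 CPM 0, 0 and 0. Leaving out 1 library at a time gave 0 to 1, 0 to 7 and 0 to 448. In delta-like cells (0, 0 and 0), median-of-ratios factors gave 17 and 13 against non-pregnant (all with a whole group at 0), no minimum level 2736, 2884 and 1652, the minimum mean of 1000 CPM 4 for postpartum against non-pregnant (Malat1, Meg3, Ubb, Tpt1), and leaving out pregnant 1 gave 74 there (68 with a whole group at 0). In gamma-like cells (63, 102 and 193, all with a whole group at 0), median-of-ratios factors gave 277, 595 and 563 (all with a whole group at 0), no minimum level 3539, 3276 and 2071, and DESeq2, edgeR, edgeR without pregnant 2 and the minimum mean of 1000 CPM 0, 0 and 0 each, with 89 for postpartum against non-pregnant without pregnant 1 (all with a whole group at 0).

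Of gene lists (1, 4 and 3 called), an estimated correlation gave 0, 0 and 0 and fry 0, 0 and 0, and leaving out 1 library at a time gave 1 to 2, 3 to 4 and 1 to 4. The secretory granule list between postpartum and pregnant passed camera with median-of-ratios factors (adjusted p = 1.59e-07) and with hormones left out (adjusted p = 0.00618). Blocking by replicate number gave 0 genes in beta-like cells (13 unadjusted) and 1 in alpha-like cells for postpartum against pregnant. The correlation of same-number libraries was 0.0093 in beta-like and -0.0518 in alpha-like cells. It cannot tell whether the numbers pair the libraries, since its pregnant side is pregnant 1 against the shallow pregnant 2.

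For shares, a minimum of 500 UMIs gave 32.8% beta-like cells in pregnant 1 and 80% (59.3 to 93.2) of only 25 cells in postpartum 1. Mixed barcodes were 0% (up to 13.7%) of these 25 cells and 0.444% in postpartum 2. A minimum of 1000 UMIs gave 38% and 69.5% beta-like cells in pregnant 1 and postpartum 2 and mixed barcodes of 51.1% and 0%. Marker scores gave 61.6%, 65.4%, 72.4%, 70.9% and 72.7% beta-like cells and 25.1%, 26.9%, 6.75%, 8.89% and 11.3% gamma-like cells. Tests at a minimum of 1000 UMIs had no residual degrees of freedom and were not run, nor were tests of other classes at 500 UMIs.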

Other observations

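Tests chosen after the result was seen were the share of the shift found in alpha-like cells, the immediate early genes in alpha-like cells and the UMIs of the mixed barcodes. The other tests here had their outcomes written down before they were run, but the depth check and the beta-like check that leave the lactogen and free RNA tests undecided were added after.

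Rpl12, a protein of the large ribosomal subunit, stood at 615 CPM in non-pregnant beta-like cells, 14.9 CPM in pregnant 1, 0 in pregnant 2 and postpartum 1, and 518 CPM in postpartum 2. In beta-like cells Txnip, an inhibitor of thioredoxin, stood at 625 and 367 CPM postpartum against 158 CPM in pregnant 1, 0 in pregnant 2 and 91.98 CPM in the non-pregnant library. In alpha-like cells Pcsk2, a prohormone convertase named here after its values were seen, stood at 21449 and 30587 CPM postpartum, 18782 and 12070.3 CPM in pregnancy and 9807 CPM in the non-pregnant library.

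In beta-like cells 22 of 2458 genes stood at least 2 log2 units from the non-pregnant library, in 1 direction, in pregnant 1 and both postpartum libraries, 8 higher (Ubb and Mafa among them) and 14 lower (Tpt1, Gpx4 and Rps6 among them). Reads shared with near-identical copies are a candidate explanation: 54.5% (interval 32.2 to 75.6) of these genes had a copy of at least 95% identity over at least 100 nt at the last 400 nt of the transcript, against 6.98% of 2421 other genes and a median of 9.09% in matched draws (Fisher's exact p = 6.45e-09). Library processing that acts on every cell class is another: the median shift in alpha-like cells was 100.4% (83.2 to 117) of that in beta-like cells, with 22 of 22 genes in the same direction. Mafa and Wipi1 shifted by only 0.96 and 0.82 there, but alpha-like cells held little of either. Mafa stood at 0 CPM in the non-pregnant library and at 92.9, 114 and 78.8 CPM in pregnant 1, postpartum 1 and postpartum 2. Wipi1 stood at 76.6 CPM and at 0 in those 3, whose 3-count limits were 103, 302 and 74.1 CPM. Their small shifts therefore do not speak against processing. The shift of genes without a copy (Tpt1 and Mafa among them), and a difference of pregnant and postpartum islets from non-pregnant ones, stay open, the latter untested since the non-pregnant group has 1 library, in a file made differently.

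Immediate early and lactogen response genes were higher in postpartum than in pregnant 1 beta-like cells. Stress of tissue handling may account for the immediate early part, since that list was higher in alpha-like cells too, with a median of 1.49 (0.50 to 2.45) against 1.51 in beta-like cells and 17 of 18 members higher. The same stress stays open for the lactogen part: postpartum beta-like cells with no immediate early UMI had lactogen levels 2.43 (2.06 to 2.83) and 2.23 (1.91 to 2.55) times that of pregnant 1, but depth alone would leave 113 of these 152 and 77.4 of these 157 cells without such a UMI, so they are not a group free of stress. Processing that acts on every class stays open for it too, as summed lactogen genes were also higher in postpartum alpha-like cells, by 1.247 (0.78 to 1.71) and 1.02 (0.66 to 1.45) on the log2 scale against 1.08 and 1.22 in beta-like cells. A response of the islet to the postpartum state stays open and was not tested.

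Barcodes with transcripts of several hormones were frequent in the non-pregnant and pregnant 1 libraries. Pairs of cells under 1 barcode would carry more UMIs than single ones, but the median of these barcodes was 0.892 (2108 against 2363) and 0.851 (434 against 510.0) times that of beta-like cells. Free RNA stays open: the variance of Gcg, Sst and Ppy over these barcodes was up to 41.1 times (lowest hormone 17.8) the binomial one in the non-pregnant library and up to 4.28 times (lowest hormone 3.72) in pregnant 1. These values pass the bound of 2 set beforehand and exceed those of the same hormones in beta-like cells, but the latter (7.40, 1.88 and 13.5 times for Gcg, Sst and Ppy in the non-pregnant library, 2.73, 2.66 and 2.48 in pregnant 1) mostly pass it too, at fewer UMIs (3.45 against 59.2 per barcode for Gcg in the non-pregnant library), so the bound does not tell free RNA apart. A mixture of own and free RNA, merged barcodes of shallow cells, and cells that express several hormones were not tested and stay open.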
